A study of Homo sapiens with 10 samples.

How the data were processed

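Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in MCF7, an established human breast cancer cell line that carries the estrogen receptor. Per the labels, cells were left untreated or given 10 nM estradiol for 30 min before fixation with formaldehyde and sonication. The 10 libraries are of 5 kinds, each made once without and once with estradiol. They are input chromatin, an immunoprecipitate with an antibody to GFP as the control, an immunoprecipitate with antiserum 3116 to DNA topoisomerase II alpha (TOP2A), and immunoprecipitates with antisera 30400 and 3535 to DNA topoisomerase II beta (TOP2B). Per the labels' protocols, several immunoprecipitates were pooled for each TOP2B antiserum and for GFP before library preparation, and the input and TOP2B libraries were sequenced repeatedly. The protocols do not say either of the TOP2A libraries.

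The values are raw read counts per region in a table the authors deposited for the whole series, with 1 column per library. The submitters' processing notes name Trimmomatic 0.39, BWA 0.7.18, HTSeq 2.0.7 and the T2T-CHM13 genome. Their settings, the removal of duplicate reads, the minimum mapping quality and the merging of repeat runs are not given in the sources used here. T2T-CHM13 is a human assembly that runs through the centromeres. The 2523 regions of the table cover centromeric and pericentromeric repeats and the transition sequence beside them. Their names give a class, a chromosome and a running index. The classes were read as the usual names of satellite annotation on this assembly. They are alpha-satellite higher-order arrays (hor), divergent higher-order arrays (dhor), monomeric alpha satellite (mon) and human satellites 1A, 1B, 2 and 3 (hsat1A, hsat1B, hsat2, hsat3). The others are beta satellite (bsat), gamma satellite (gsat), other satellites (censat), ribosomal DNA (rDNA) and the transition sequence between or beside arrays (ct). The 856 ct regions, some named p_arm or q_arm, held 78.55% to 87.97% of the reads in regions. The table gives no coordinates, and the region names give no gene. The gene table at hand belongs to another assembly and was not used. No count of the table was left unmapped to a library.

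The last 5 rows of the table are summary rows and stayed out of the tests and library sizes. Reads outside any region made up 64.4% to 76.7% of all reads, reads of low mapping quality 18.5% to 31.1%, and ambiguous reads under 0.01% in each library. Reads of low mapping quality were not counted in any region, so values of repeats cover only reads that could be placed. Satellite copies resemble each other, so a placed read can still belong to a near-identical copy, and values of single regions are uncertain to that extent.

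Differences were tested with the edgeR quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on the deposited counts. Library sizes were the reads in regions with trimmed mean of M-values (TMM) factors. Regions were kept by filterByExpr with the kind of library as the group (minimum count 10, minimum total 15), which left 1548, and 306 regions had no read in any library. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. All 10 libraries entered each model. Comparisons between kinds used a model of kind plus estradiol, with 4 residual degrees of freedom, and the mean of both antisera stood for TOP2B. The estradiol comparisons used a separate estradiol term for TOP2B, TOP2A and the controls (input and GFP), with 2 residual degrees of freedom, and subtracted the change in the controls. No group has a second library. The spread therefore comes from the disagreement between libraries of a kind, or between kinds of a class, and p-values measure that spread, which may be technical. The comparisons with input, GFP over input, TOP2A versus TOP2B, antiserum 3535 versus 30400 and the estradiol effects were fixed before the data were examined. TOP2B over GFP and TOP2A over GFP as comparisons of their own, and the estradiol effect in TOP2A minus that in TOP2B, were added afterwards. A standard error (SE) is the log2 fold change divided by the square root of F.

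Feature lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. Of 25 lists fixed before the data were examined, 4 had members in the table: alpha satellite, human satellites 1 to 3, other satellites and ribosomal RNA. The 12 classes of the region names were added as lists afterwards. Named regions had an adjusted p under 0.05, a mean count of at least 20 and the same sign without and with estradiol, up to 12 per direction. Where fewer than 5 passed, the 6 largest per direction with a mean count of at least 100 are given as values that did not pass. Up to 4 members with the highest count of each list are named too. The sign condition has no counterpart for the estradiol effect on TOP2A, with a single antiserum, and was not applied there. Regions of the Y chromosome are not named, but they stay in the tests and in the counts of calls.

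Shares of a class are percentages of the reads in regions, compared by two-sided exact permutation tests over libraries, adjusted over the 13 measures of each contrast. Intervals of single libraries are 95% Wilson intervals. A fold against libraries without a read is a lower bound against a floor of 3 counts per library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Reads in regions ranged from 294200 to 1349648 per library. The median SE of TOP2B over input was 0.90 (log2) over all tested regions and 0.10 over the 103 with a mean count of at least 1000.

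Each model was tested on simulated counts with 200 of 1548 regions changed. The simulation gave every library the same spread per region. The kinds of library differed in spread, so the shares below hold for equal spread only. For TOP2B over input, 12.2% of regions changed 2-fold and 35.2% of those changed 4-fold were recovered, with 4.44% false calls, and 63.2% and 97.6% among regions with a mean of at least 200 normalised counts (edgeR cpm). For the estradiol effect on TOP2B the recovered shares were 4.4% and 16.8%, with 13.8% false calls. Among regions with that mean they were 26.4% and 78.4%, with 5.24% false calls. For the estradiol effect on TOP2A they were 1.8% and 9%, with 10% false calls, and 13.6% and 51.8%, with 5.49%, among regions with that mean. The false share of these models thus lay above the nominal threshold. Alternatives were DESeq2 size factors, library totals in regions or over all reads, the DESeq2 Wald test (DESeq2 1.42.0), no filter or a mean count of at least 50, each library left out in turn, GFP or both controls as the background, a model without an antiserum term, other controls for estradiol, and limma voom with library weights. Comparisons with input were also correlated with each side against the input library of its own treatment, on log2 counts with a prior count of 2.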

Results

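Occupancy of both type II DNA topoisomerases in centromeric and pericentromeric regions was measured in MCF7 breast cancer cells. Cells were taken without estradiol and 30 min after its addition at 10 nM. TOP2A and TOP2B pass DNA duplexes through each other. TOP2A acts mainly in dividing cells, and TOP2B is present throughout the cell cycle and at hormone-responsive promoters. The 10 libraries were input, GFP antibody control, TOP2A antiserum 3116, TOP2B antiserum 30400 and TOP2B antiserum 3535, each once without and once with estradiol. All reads per library ranged from 6157485 in the GFP control with estradiol to 29554321 in input with estradiol. Reads in the 2523 regions ranged from 294200 in that GFP library to 1349648 in untreated input, or 4.51% to 4.91% of all reads. The TOP2A libraries held 521100 (untreated) and 698017 (estradiol) reads in regions, and the TOP2B libraries 900074 to 1312068.

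Libraries of a kind differed to very different degrees. The biological coefficient of variation between the library without and the library with estradiol was 0.0426 for input, 0.0552 for GFP, 0.397 for antiserum 3535, 0.674 for antiserum 30400 and 1.25 for TOP2A. Input and GFP pairs still differed by more than the counting error of independent reads (chi-square per degree of freedom 1.99 and 1.79). They were counted as separate libraries because the labels give them so. Of the regions where at least 30 reads were expected from the other immunoprecipitates, 85 of 669 (12.7%) held at most 0.1 of that number in untreated TOP2A and 10 of 746 (1.34%) in TOP2A with estradiol. No such region occurred in either GFP library.

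The comparison of TOP2B with input asks which regions are over- or under-represented in the TOP2B immunoprecipitates. Human satellites 2 and 3, the large tandem arrays of pericentromeric heterochromatin, were lower in TOP2B than in input. All 48 regions called lower belonged to them, 37 to hsat3 and 11 to hsat2. All 29 regions called higher were transition regions (ct), by less than 2-fold. The share of hsat3 in region reads was 2.92% ± 0.23 (SD, n = 4) in TOP2B and 8.28% ± 0.51 (SD, n = 2) in input. Among the most abundant members of the human satellite list, hsat3_20_3(B3,A1,A2) on chromosome 20 fell by 1.47 on the log2 scale (SE 0.11, adjusted p = 0.000141, edgeR), hsat2_1_6(A2,A1,B) on chromosome 1 fell by 1.35 (SE 0.12) and hsat3_9_3(B5) on chromosome 9 fell by 1.29 (SE 0.13). Of the regions named by the rule, hsat3_22_16(A1,A4) showed a log2 ratio of -1.86 (SE 0.39), hsat2_2_6(B) -1.77 (SE 0.26) and hsat3_10_2(A2) -1.57 (SE 0.14). hsat3_16_5(A4) on chromosome 16 had no read in either library of antiserum 30400, against 46 and 44 in those of antiserum 3535 and 140 and 129 in input. Of the 12 named higher, ct_12_11 (0.66, SE 0.13), ct_3_1(p_arm) (0.65, SE 0.06) and ct_6_7(q_arm) (0.63, SE 0.08) were among the largest.

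By list, 48 of 196 human satellite 1 to 3 regions fell and 148 did not pass, with 84 lower when adjusted over the list alone. Their median log2 ratio was -1.41, and the list ranked below the other regions (camera adjusted p = 5.18e-60, and adjusted p = 0.00110 with an estimated correlation). None of the 339 alpha-satellite regions, the 368 other-satellite regions or the 5 ribosomal DNA regions passed. The list of alpha satellite had a median of -0.35 (camera adjusted p = 0.0683), other satellites 0.02 (0.365) and ribosomal RNA -0.39 (0.731). In alpha satellite, mon_5_1 gave 0.21 (SE 0.11) and mon_11_3 0.22 (SE 0.13). In other satellites, bsat_22_1(LSAU-BSAT_Composite) gave -0.38 (SE 0.12) and bsat_1_1(LSAU-BSAT_Composite) -0.06 (SE 0.14). DESeq2 called 131 regions and limma voom with library weights 266, against 77 in edgeR. With library totals in place of TMM the median of all regions moved by -0.13 and 76.8% of the calls were lower, against 62.3%. The total was 181 and 179 without the untreated and the treated TOP2A library, 41 and 44 without those of antiserum 3535, and 38 and 37 without those of input.

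The comparison of TOP2A with input asks the same of TOP2A. Human satellites 2 and 3 were lower here too, and they made up 68 of the 81 regions called lower, 51 of them hsat3 and 17 hsat2. The others were 5 hor, 2 bsat, 2 censat, 2 ct, 1 dhor and 1 mon region. Of the 29 called higher, 28 were transition regions and 1 was monomeric alpha satellite. hsat3_22_10(A4,A2) on chromosome 22 fell by 2.54 on the log2 scale (SE 0.26), hsat3_20_3(B3,A1,A2) fell by 1.90 (SE 0.13, adjusted p = 7.78e-05, edgeR) and hsat2_1_6(A2,A1,B) fell by 1.67 (SE 0.15). Among the largest decreases named by the rule, 8 regions had no read in either TOP2A library and were at least 4.57-fold to at least 25.1-fold lower than in input, from bsat_7_9 to hsat3_14_18(A4). The regions hsat2_7_16(B) and dhor_18_4(SF2) held 1 and 14, and 1 and 3, TOP2A reads, against 518 and 419, and 94 and 88, in input. Higher regions included mon_8_11 (1.51, SE 0.22), ct_1_2 (0.93, SE 0.16) and ct_3_1(p_arm) (0.82, SE 0.07).

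By list, 68 of 196 human satellite regions fell, and 102 were lower when adjusted over the list alone. Their median log2 ratio was -2.02, or -1.88 with regions without a TOP2A read at their bound (camera adjusted p = 5.17e-33, and adjusted p = 0.00181 with an estimated correlation). In alpha satellite 1 region rose, 7 fell and 331 did not pass (median -0.76, camera adjusted p = 0.0788). In other satellites 4 fell and 364 did not pass. That list had a median of -0.21 while camera placed it above the other regions, without passing (adjusted p = 0.162). The 5 ribosomal DNA regions did not pass (median -0.22, camera above the others, adjusted p = 0.694). DESeq2 called 228 regions, against 110 in edgeR. The total was 598 without the treated TOP2A library, 192 without the untreated one, 68 and 71 without those of antiserum 3535, and 60 without either input library.

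**Figure D1:**
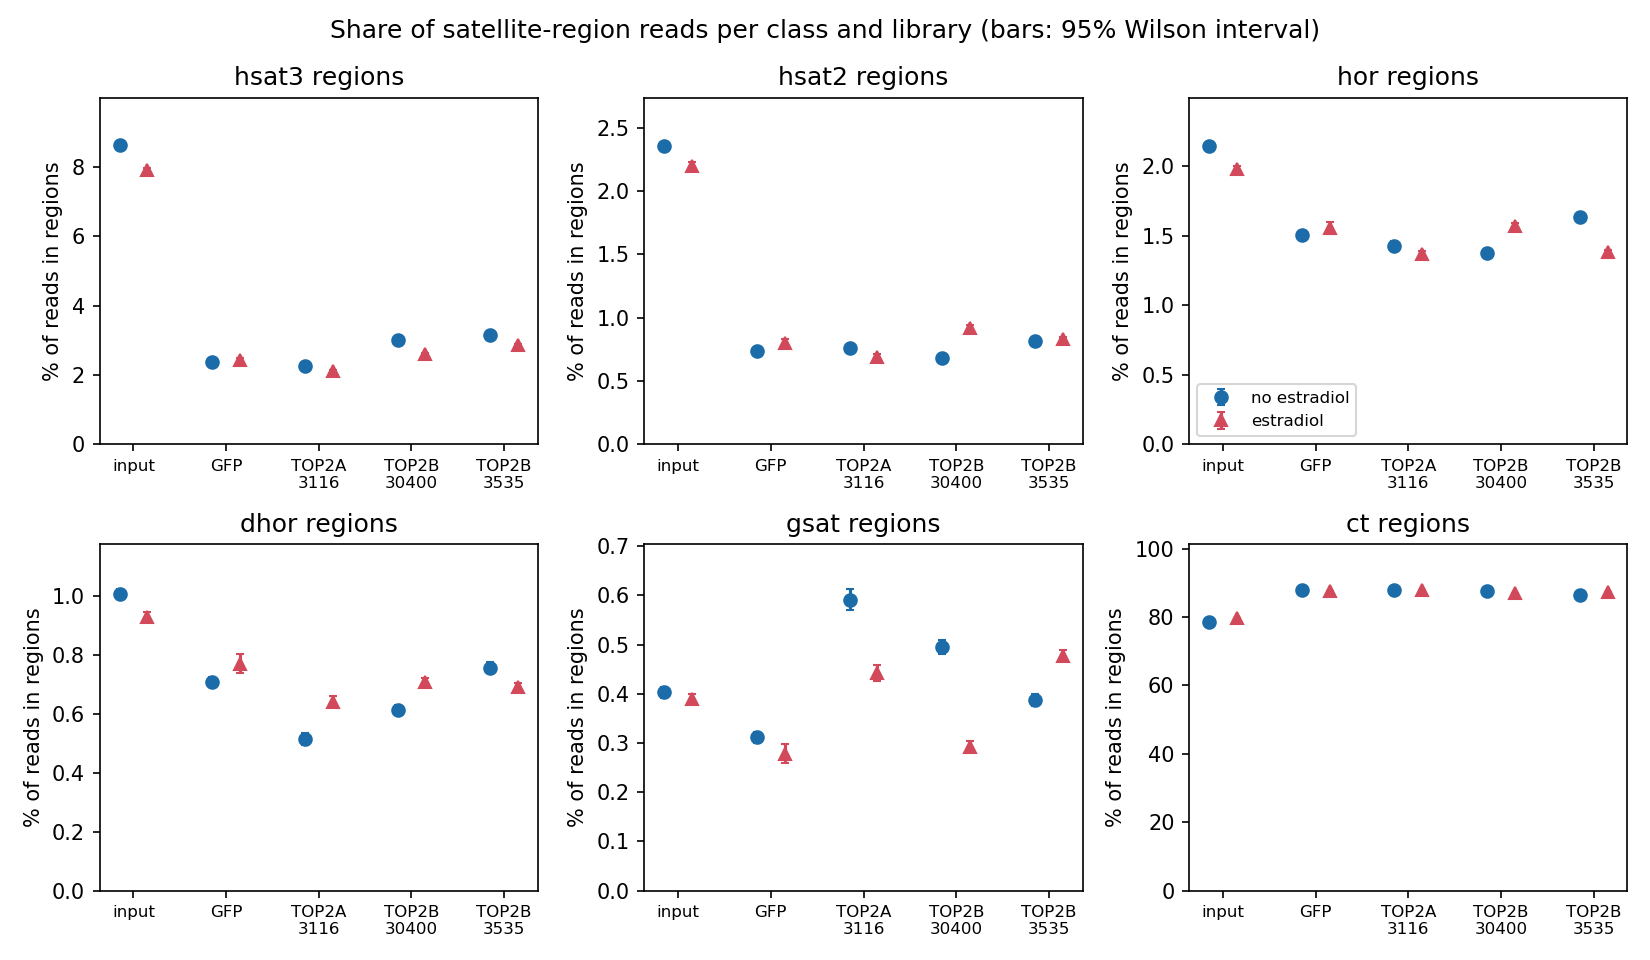
Percent of the reads in regions that fell in 6 classes of region, for each library without (circles) and with estradiol (triangles). Each axis starts at 0, and bars give 95% Wilson intervals that cover counting error only. The hsat3 share was 8.64% and 7.92% in the input libraries and between 2.11% and 3.17% in the 8 immunoprecipitates, those with the GFP antibody included.

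The GFP control shows how an immunoprecipitate without a TOP2 antibody differs from input. Human satellites 2 and 3 were lower in it as well. All 47 regions called lower were hsat3 (38) or hsat2 (9), and all 31 called higher were transition regions. hsat3_17_4(A2) on chromosome 17 fell by 2.07 on the log2 scale (SE 0.27), hsat3_13_6(B3) on chromosome 13 fell by 2.02 (SE 0.22) and hsat3_20_3(B3,A1,A2) fell by 1.71 (SE 0.13, adjusted p = 1.00e-04, edgeR). ct_12_11 rose by 1.01 (SE 0.14) and ct_3_1(p_arm) by 0.87 (SE 0.07). The human satellite list had a median of -1.58, or -1.53 with regions without a GFP read at their bound, and 77 lower when adjusted over the list alone (camera adjusted p = 1.14e-42, and adjusted p = 0.00202 with an estimated correlation). Alpha satellite (median -0.15, adjusted p = 0.558), other satellites (-0.07, 0.558, camera above the others) and ribosomal RNA (-1.29, 0.384) did not pass.

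Across the 8 immunoprecipitates, hsat3 took 2.60% ± 0.38 (SD) of region reads, against 8.28% in input, hsat2 0.780% ± 0.079 against 2.28%, and the hor arrays 1.48% ± 0.10 against 2.06%. Transition regions took 87.5% ± 0.47 against 79.2%. Shares are parts of the same total, so this difference (8.33 points) is not separate from those in hsat3 (-5.68) and hsat2 (-1.50). Each of these differences had an exact permutation p of 0.0222, the smallest that 45 splits allow, and an adjusted p of 0.0481. The test takes libraries as exchangeable, although they are of different kinds and no group has a second library. The adjusted value rests on several measures tied at the smallest p, most of them parts of the same total. The share of reads of low mapping quality was 19.9% ± 1.0 in the immunoprecipitates and 31.0% ± 0.13 in input, with the same exact p.

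The comparisons with input share the same input libraries. TOP2B and GFP shared 26 regions higher and 41 lower, against 0.581 and 1.46 expected of independent lists. The covariance of their log2 ratios across regions was 0.575, against 0.0655 in simulated data with unchanged groups and the same controls, and Pearson's r was 0.377 against 0.187. TOP2A and GFP shared 22 higher and 43 lower (covariance 1.07, simulated 0.0862). TOP2B and TOP2A shared 21 higher and 44 lower (covariance 0.837, simulated 0.203). Regions are not independent replicates. With each side set against the input library of its own treatment, so that no library was shared, r was 0.277 and 0.511 for TOP2B with GFP (TOP2B untreated, then treated), 0.214 and 0.400 for TOP2A with GFP, and 0.307 and 0.259 for TOP2B with TOP2A. Each side then keeps 1 input library, and part of the excess in the full comparisons may come from the shared controls. In GFP over input, DESeq2 called 81 lower and limma voom with library weights 266 higher and 320 lower. Library totals in place of TMM moved the median by -0.17 and made 73.0% of the calls lower, against 60.3%. The 78 calls became 185 and 183 without the untreated and the treated TOP2A library, 51 and 53 without those of antiserum 3535, 36 and 41 without those of GFP, and 43 and 42 without those of input.

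**Figure D2:**
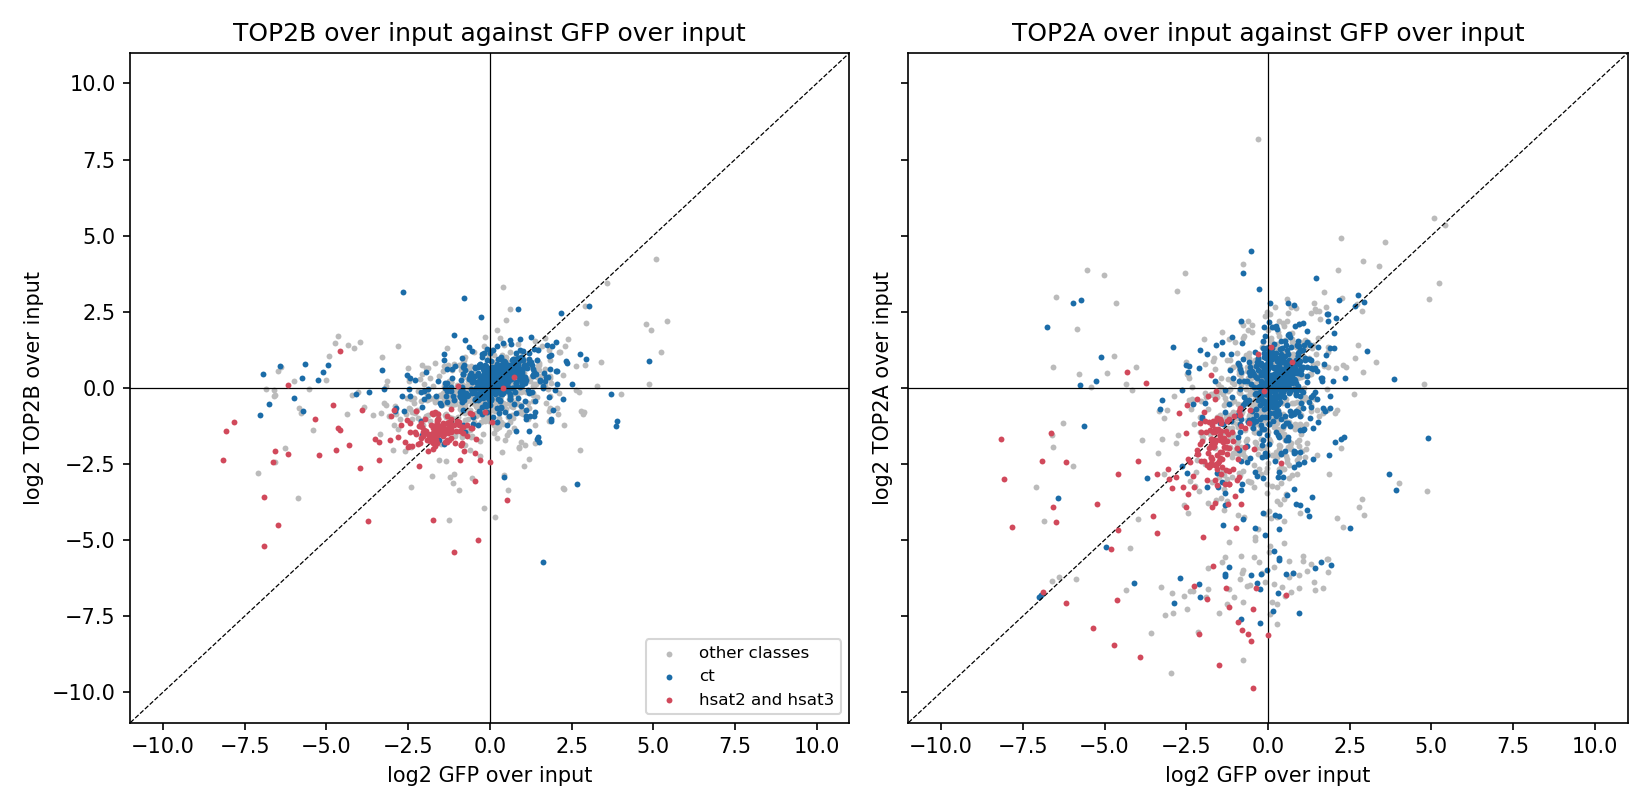
Each point is 1 of 1548 tested regions, with log2 GFP over input on the horizontal axis and log2 TOP2B over input (left) or TOP2A over input (right) on the vertical axis, and the dashed line marks equal values. Most of the 175 human satellite 2 and 3 regions (red) lie below 0 on both axes, with medians of -1.62 for GFP, -1.45 for TOP2B and -2.19 for TOP2A. With regions without a read at their bound, the medians of GFP and TOP2A were -1.58 and -1.97. Over all 1548 regions the medians were -0.03 for GFP, -0.04 for TOP2B and -0.35 for TOP2A. Points beyond about -5 are fitted values of regions with few or no reads.

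The comparison of TOP2 with the GFP control asks what the TOP2 antisera bring down beyond an unrelated antibody. No region was called for TOP2B over GFP in edgeR (86 of 1548 at an unadjusted p under 0.05, smallest adjusted p = 0.849) or in DESeq2, whereas limma voom with library weights called 51 higher and 40 lower. Values that did not pass in edgeR included gsat_8_13(GSAT) at 1.03 (SE 0.37), hor_1_2(S3C1H2-A,B) at 1.27 (SE 0.41), hsat3_14_12(A1,A4) at 1.46 (SE 0.44), ct_19_34 at -0.81 (SE 0.20) and mon_18_1 at -0.99 (SE 0.34). Among the 103 regions with a mean count of at least 1000, log2 TOP2B over GFP lay between -0.38 and 0.65, and the 95% intervals of single regions reached from -0.72 to 1.07. The model takes part of its spread from the TOP2A pair (coefficient of variation 1.25, against 0.674 and 0.397 for the TOP2B antisera and 0.0552 for GFP). The absence of calls therefore cannot exclude TOP2B signal over GFP. The hsat3 share was 2.92% ± 0.23 (SD, n = 4) in TOP2B and 2.40% ± 0.041 (SD, n = 2) in GFP. All 4 TOP2B libraries lay above both GFP libraries, with an exact permutation p of 0.0667 (adjusted p = 0.65 over 13 measures). The unadjusted value is the smallest that 15 splits allow, so the design cannot pass 0.05 here.

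The human satellite list had a median of 0.19 in TOP2B over GFP (camera adjusted p = 0.162) and the hsat3 class, added as a list afterwards, 0.24 (camera adjusted p = 0.0294, but adjusted p = 0.978 with an estimated correlation). Alpha satellite (-0.08, adjusted p = 0.198), other satellites (0.06, 0.804) and ribosomal RNA (1.04, 0.198) did not pass. For TOP2A over GFP, edgeR called no region either (245 at an unadjusted p under 0.05, smallest adjusted p = 0.240), DESeq2 called 20 higher and 43 lower, and limma voom 6 and 1. gsat_8_12(GSAT) gave 1.54 (SE 0.42), gsat_X_1(GSATX) 1.32 (SE 0.49), mon_15_9 1.34 (SE 0.42) and mon_15_1 -2.06 (SE 0.72). The TOP2A reads of mon_15_1 were 6 without and 81 with estradiol. The medians were -0.31 for human satellites (adjusted p = 0.211, and 2 regions lower when adjusted over the list alone), -0.50 for alpha satellite (0.129), -0.06 for other satellites (0.211, camera above the others) and 0.82 for ribosomal RNA (0.152). Without the treated TOP2A library 137 regions were higher and 381 lower than GFP, and without the untreated one 2 and 29. For TOP2B over GFP, leaving out either TOP2A library gave 5 higher and 3 lower.

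TOP2A was compared with TOP2B to find regions that differ between the paralogs. No region was called in edgeR (236 of 1548 at an unadjusted p under 0.05, smallest adjusted p = 0.140), whereas DESeq2 called 24 higher and 63 lower in TOP2A, and limma voom with library weights called none. Large values that did not pass included hsat2_7_16(B) on chromosome 7 at -3.46 (SE 0.68), hsat3_22_14(B3) at -2.70 (SE 1.04) and mon_15_1 at -2.04 (SE 0.66) below 0. Those above 0 included mon_17_4 at 1.11 (SE 0.60), hor_4_1(S2C4H1L) at 1.09 (SE 0.40) and ct_9_30 at 1.05 (SE 0.36). Each of these was larger in size without estradiol than with it. The log2 differences without and with estradiol were 2.23 and 0.02 for mon_17_4. They were -6.83 and -0.92 for hsat3_22_14(B3) (0 and 35 TOP2A reads) and -4.27 and -0.91 for mon_15_1 (6 and 81). The human satellite list was lower in TOP2A (median -0.56, camera adjusted p = 0.0138, but adjusted p = 0.303 with an estimated correlation), and 20 of its 196 regions were lower and 1 higher when adjusted over the list alone. Of the classes added afterwards, hsat3 was lower in TOP2A (median -0.78, camera adjusted p = 0.000539) and hsat1A higher (1.26, 0.00766), and neither passed with an estimated correlation (adjusted p = 0.352 and 0.430). The hsat1A difference did not hold against each antiserum: its share of region reads was 0.0434% and 0.0274% in TOP2A (untreated and treated), 0.0246% and 0.0395% with antiserum 30400, and 0.00913% and 0.00907% with antiserum 3535. Alpha satellite (-0.44, adjusted p = 0.248), other satellites (-0.17, 0.248, camera above the others) and ribosomal RNA (-0.22, 0.400, camera above the others) did not pass. Without the treated TOP2A library 162 regions were higher and 405 lower, and without the untreated one 8 and 47. Without either input library 1 was lower, and with no filter on low counts 10 were.

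The 2 antisera to TOP2B were compared to see whether they bring down the same regions. No region was called in edgeR (40 of 1548 at an unadjusted p under 0.05, smallest adjusted p = 1), DESeq2 called 1 higher with antiserum 3535, and limma voom with library weights called 1 higher and 6 lower. Large values that did not pass included ct_22_42 at 1.32 (SE 0.48), mon_14_9 at 0.97 (SE 0.72) and hsat3_15_2(B4) at 0.84 (SE 0.34) above 0, and ct_21_18 at -0.97 (SE 0.66), ct_8_2 at -0.83 (SE 0.34) and mon_6_2 at -0.82 (SE 0.39) below 0. Among the 103 regions with a mean count of at least 1000, the log2 difference lay between -0.45 and 0.36, and the intervals of single regions reached from -0.94 to 0.90. Part of the spread in this model comes from the TOP2A pair (coefficient of variation 1.25, against 0.674 for antiserum 30400 and 0.397 for 3535). The absence of calls therefore does not show that the antisera agree. Medians were 0.01 for alpha satellite, 0.09 for human satellites, 0.09 for other satellites and 0.02 for ribosomal RNA (adjusted p = 0.985, 0.985, 0.209 and 0.985, camera). Of the classes added as lists afterwards, hsat1A was lower with antiserum 3535, with 11 of 12 regions below 0 (median -1.83, camera adjusted p = 2.43e-07, but adjusted p = 0.127 with an estimated correlation). The whole class held few reads, 89 and 119 with antiserum 3535 (untreated and treated) and 221 and 419 with antiserum 30400. Relative to GFP, the antisera in libraries that share none correlated across the 1548 regions with Pearson's r of 0.391 (30400 untreated with 3535 treated) and 0.272 (30400 treated with 3535 untreated). The untreated and treated TOP2A libraries gave r = 0.127 in the same way. The GFP libraries closely resembled each other (Spearman's rho = 0.956). A departure particular to GFP thus enters both sides, so r cannot separate it from TOP2B signal shared by the antisera. Without either TOP2A library 1 region was higher with antiserum 3535.

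The estradiol effect on TOP2B asks whether 30 min of hormone moves TOP2B in these regions beyond the change in the controls. No region was called in edgeR (30 of 1548 at an unadjusted p under 0.05, smallest adjusted p = 0.998) or DESeq2. Values that did not pass, with the same sign in both antisera, included hsat2_16_12(B) at 1.03 (SE 0.30), bsat_19_36 at 1.26 (SE 0.58), hsat3_22_14(B3) at -1.37 (SE 0.51) and hsat3_22_17(B3) at -0.89 (SE 0.53). The 5 ribosomal DNA regions had a median of -1.41, and all lay below 0 (camera adjusted p = 0.00747, but adjusted p = 0.742 with an estimated correlation). Their reads went from 385 to 136 with antiserum 30400 and from 287 to 339 with antiserum 3535, which is 0.0428% to 0.0128% and 0.0294% to 0.0258% of region reads. The GFP control went from 0.0164% to 0.0217%. Alpha satellite (median 0.13, adjusted p = 0.531), human satellites (0.01, 0.881, camera below the others) and other satellites (0.13, 0.881) did not pass.

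Among the 103 regions with a mean count of at least 1000, the estradiol effect on TOP2B lay between -0.47 and 0.60, and the 95% intervals of single regions reached from -1.28 to 1.19. The estradiol changes of the antisera did not correlate across the 1548 regions (Pearson's r = -0.00899, Spearman's rho = -0.0156), and r was -0.304 over the 103. Without a library of antiserum 30400 edgeR called 50 (untreated left out) or 51 (treated left out) regions, and without a library of antiserum 3535 434 or 427. TOP2B and TOP2A then have no repeated estradiol difference, and the spread comes from input and GFP alone.

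The estradiol effect on TOP2A asks the same of TOP2A, with 1 antiserum and so 1 pair of libraries. After estradiol 153 regions were called higher and 41 lower in edgeR, and 132 and 40 in DESeq2. The higher ones were 49 ct, 24 mon, 18 censat, 17 hsat3, 14 bsat, 12 hor, 8 dhor, 8 hsat2, 2 gsat and 1 rDNA region, and the lower ones 18 ct, 7 hsat3, 6 censat, 3 hsat2, 2 mon, 2 dhor, 1 bsat, 1 gsat and 1 hor. All 12 regions named higher had no read in untreated TOP2A and were at least 18.03-fold to at least 39.9-fold higher with estradiol. mon_14_11 on chromosome 14 held 0 and 155 TOP2A reads, against 209 and 55 in GFP. hsat3_22_22(A4) held 0 and 147 and bsat_7_2 0 and 134. Of the 12 named lower, 7 had no read with estradiol and were at least 17.7-fold to at least 60.4-fold lower. ct_2_41 held 140 and 0 TOP2A reads, against 21 and 11 in GFP, and censat_20_12(HSat5) 111 and 0. Of abundant regions, hsat3_22_10(A4,A2) rose by 1.05 (SE 0.21, adjusted p = 0.0208, edgeR). Its normalised counts in TOP2A were 485 and 959 (untreated and treated), both below those in GFP (1386 and 1390). rDNA_15_1 on chromosome 15 rose by 3.35 (SE 0.91, adjusted p = 0.0477). It held 7 and 62 TOP2A reads. GFP held 38 and 5 (42.0 and 17.6 normalised counts), and that fall is part of the control change subtracted.

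In the 153 higher regions untreated TOP2A lay at a median log2 of -3.21 against the other immunoprecipitates (77 regions without a read at their floor) and was the lowest of the 8 in 152. TOP2A with estradiol lay at 0.26 in them. In the 41 lower regions untreated TOP2A lay at 1.47 and TOP2A with estradiol at -1.86, the lowest of the 8 in 38. None of the lists passed: alpha satellite with 44 higher, 5 lower and 290 not passing (51 and 9 adjusted over the list alone), human satellites with 25, 10 and 161 (30 and 14), other satellites with 34, 8 and 326 (33 and 7), and ribosomal RNA with 1, 0 and 4 (2 and 0), each at a camera adjusted p = 0.705. The model assumes that the TOP2A pair varies like the other pairs, whereas its variation was the largest. Data simulated with no estradiol effect and the spread of each pair of libraries gave a median of 246.5 calls (155 to 318, 20 simulations), although that spread includes any estradiol effect. The 194 calls became 786 and 792 without the libraries of antiserum 30400, 790 and 783 without those of 3535, 80 and 79 without those of GFP, and 81 and 83 without those of input (untreated and treated).

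**Figure D3:**
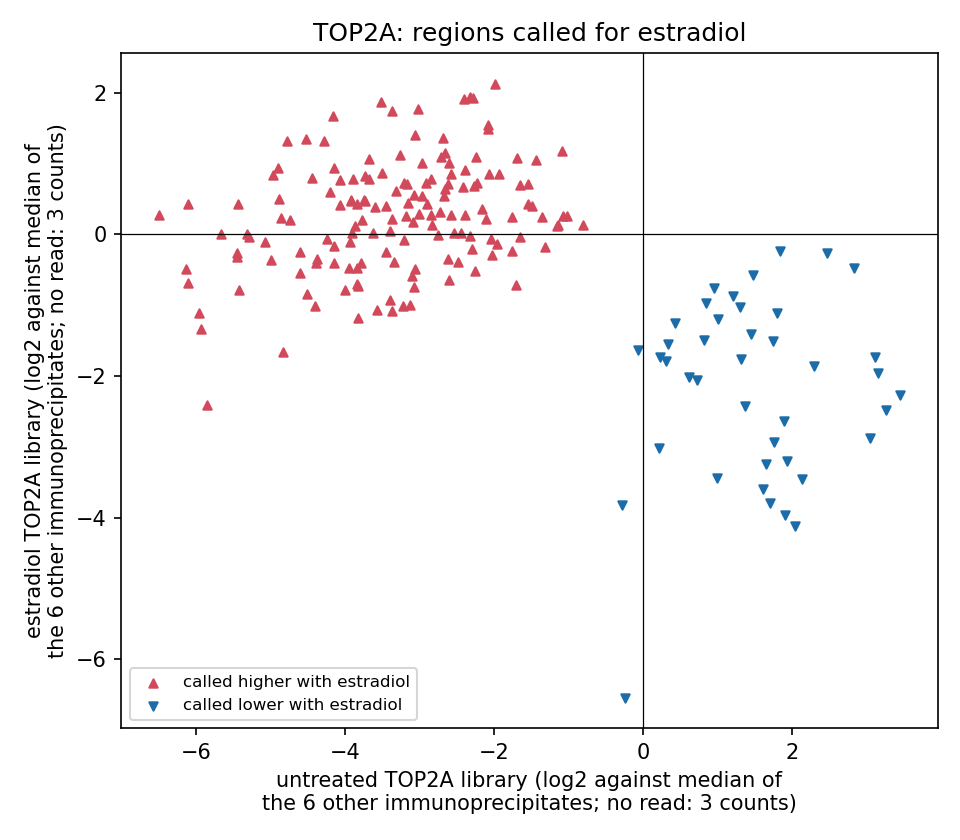
Each point is 1 of the 194 regions called for estradiol in TOP2A, with the untreated TOP2A library on the horizontal axis and the estradiol TOP2A library on the vertical axis, both as log2 against the median of the 6 other immunoprecipitates and with libraries without a read at 3 counts. The 153 regions called higher (triangles up) have medians of -3.21 and 0.26, and the 41 called lower (triangles down) 1.47 and -1.86.

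The estradiol effect in the controls gives the change in input and GFP between untreated and treated chromatin. No region was called in edgeR (0 of 1548 at an unadjusted p under 0.05) or DESeq2. Part of the spread in this model comes from the TOP2B antisera (coefficients of variation 0.674 and 0.397, against 0.0426 for input and 0.0552 for GFP). That spread is larger than the controls' own, so the absence of calls cannot exclude small changes. Large values that did not pass included ct_16_57 at 0.62 (SE 0.28), hsat2_22_4(B) at 0.57 (SE 0.33), ct_14_54 at -0.52 (SE 0.38) and gsat_8_12(GSAT) at -0.47 (SE 0.30). Medians were -0.04 for alpha satellite, -0.06 for human satellites, -0.06 for other satellites and 0.34 for ribosomal RNA (adjusted p = 0.678, 0.584, 0.678 and 0.584, camera). Among the 103 regions with a mean count of at least 1000 the change lay between -0.10 and 0.11, and the 95% intervals of single regions reached from -0.70 to 0.58.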

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

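All tests of explanations in this part were chosen after the results were seen. An interaction term in edgeR called the estradiol effect in TOP2A against that in the controls in 153 regions higher and 41 lower, and against that in TOP2B in 154 higher and 63 lower, with 166 regions in both. Both tests rest on the same single pair of TOP2A libraries, so neither shows a difference specific to TOP2A. Counts simulated with no estradiol effect and the spread of each pair gave medians of 246.5 and 279.5 calls, more than the 194 and 217 seen, although that spread includes any estradiol effect. The 24 regions named for TOP2A were chosen for extreme values in that pair, so their adjusted p against TOP2B adds no further support. It was 0.00277 for mon_14_11, hsat3_3_1(A4) and hsat3_22_22(A4), 0.00471 for hsat3_10_4(B3,A2), 0.0161 for ct_2_42, 0.0171 for bsat_7_2, 0.0147 for ct_7_39, 0.00805 for ct_15_32, 0.00207 for hsat3_14_20(A2,A4), 0.00805 for ct_20_29, 0.010 for ct_17_24 and 0.0239 for bsat_19_20 above 0. Below 0 it was 0.00805 for ct_2_41, 0.0413 for ct_19_11, 0.0209 for censat_20_12(HSat5), 0.0161 for ct_9_37, 0.0413 for hsat3_14_5(B3,A1), 0.0200 for ct_17_25, 0.0287 for censat_22_19(CCTGGCn), 0.0359 for hor_19_8(S5C5/19H5), 0.0255 for censat_20_5(SST1_Composite), 0.0209 for ct_14_16, 0.0239 for ct_14_71 and 0.0261 for dhor_3_4(S1CMH3d). Reads outside any region took 76.1% of all reads in untreated TOP2A and 76.7% in TOP2A with estradiol, above the highest control library (75.8%).

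In the regions called higher for estradiol in TOP2A, the estradiol library lay near the other immunoprecipitates and the untreated library far below them. A gain of TOP2A over the immunoprecipitation background is not enough for the set, since the estradiol library exceeded estradiol-treated GFP by a median log2 of only 0.35 (quartiles -0.22 and 1.12). An estradiol response at single regions stays open with 1 pair of libraries, as does a loss of TOP2A down to background at the regions called lower, since the median of -2.29 against GFP there (quartiles -3.17 and -1.29) comes from regions called partly for a low value in that library. Reads missing from the untreated TOP2A library are a candidate explanation for the higher regions, where it lay at a median of -3.21 against the other immunoprecipitates. Regions called for a rise are chosen partly for a low untreated value, but 12.7% of all eligible regions, called or not, were nearly empty in that library.

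TOP2 pairs of libraries differed far more than the input and GFP pairs. For TOP2A depth is argued against, since at 294200 reads per library its pair kept a chi-square per degree of freedom of 16.21 and the GFP pair 1.476. At that depth the pair of antiserum 30400 went from 21.23 to 8.363 and that of antiserum 3535 from 9.054 to 3.329. Depth may thus account for part of the TOP2B differences, most of all for antiserum 3535. A response to estradiol shared by both TOP2B antisera is argued against as the main source, by a correlation of -0.00899 between their changes. Over the 103 regions with a mean count of at least 1000 it was -0.304. A shared response at a minority of regions could be hidden by the spread and stays open. Few distinct fragments may have added to the spread of TOP2A, since 12.7% of the regions eligible for this count were nearly empty in its untreated library and none in GFP. For TOP2B the highest share was 1.31%, which leaves that explanation open, as it does a hormone response that differs between antisera.

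Human satellites 2 and 3 were lower in both TOP2 proteins than in input. A difference between immunoprecipitates and input that needs no TOP2 may account for much of it, since GFP over input had a median log2 of -1.62 over the same 175 regions. Loss of satellite reads to low mapping quality stays undecided. The share of reads of low mapping quality was 11.16 points lower in the immunoprecipitates than in input (-11.16). It counts all such reads, not those of satellites alone. All regions together held only 4.51% to 4.91% of all reads, so a shift of satellite reads could be hidden in that share. TOP2B below the background on these repeats is argued against by a median of 0.20 over GFP. For TOP2A the median was -0.32 (quartiles -1.22 and 0.21) and did not decide. Base composition could not be tested without sequence.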

How the results depend on the processing

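Limma voom with library weights, totals of all reads, TOP2B and TOP2A over GFP, the classes as lists, the comparisons with separate input libraries, the simulated test of TOP2A minus TOP2B, and the ct shares against either input were chosen after seeing the data, and the other alternatives before. The cause of each change below was not tested, except where fewer regions or libraries entered. No paired analysis was possible because the labels give no replicate numbers, beyond the estradiol term of the model, which already blocks the comparisons of kinds by treatment. No comparison has 3 libraries in each of its groups, so other splits of the samples were not counted. A stricter model for the TOP2A pair needs a second pair.

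With GFP as the background, TOP2B and TOP2A over input went from 29 and 48, and 29 and 81 (higher and lower), to 0 in each. In TOP2B, 15 named regions then changed sign, to -0.35 for ct_12_11, -0.22 for ct_3_1(p_arm), -0.20 for ct_6_7(q_arm), -0.15 for ct_5_4(q_arm), -0.11 for ct_4_1(p_arm), -0.19 for ct_3_8(q_arm), -0.15 for ct_21_69(q_arm), -0.22 for ct_12_12(q_arm), -0.14 for ct_6_1(p_arm), 0.32 for hsat3_22_16(A1,A4), 0.19 for hsat2_9_1(B), 0.20 for hsat3_15_2(B4), 0.17 for hsat3_10_2(A2), 0.30 for hsat3_22_2(B4) and 0.19 for hsat3_22_9(A4,B3). In TOP2A, 4 did, to -0.0580 for ct_3_1(p_arm), -0.0522 for ct_3_8(q_arm), -0.0011 for ct_21_69(q_arm) and -0.33 for ct_12_11. None of these passed the threshold. With the mean of both controls as background the counts were 0 and 8 for TOP2B, and 12 and 38 for TOP2A.

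With DESeq2, higher and lower counts were 47 and 84 (TOP2B over input), 69 and 159 (TOP2A over input), 24 and 63 (TOP2A versus TOP2B), and 20 and 43 (TOP2A over GFP), with 81 lower in GFP over input and 1 higher for antiserum 3535. With limma voom they were 107 and 159 (TOP2B over input), 266 and 320 (GFP over input), 51 and 40 (TOP2B over GFP), 6 and 1 (TOP2A over GFP), and 1 and 6 (antisera), with 51 lower in TOP2A over input. Library totals gave 19 higher in TOP2B and 20 in GFP over input. A mean count of at least 50 gave 55 higher in TOP2A over input. Without a filter, 10 were lower in TOP2A versus TOP2B, 1 in TOP2A over GFP, and 237 higher and 75 lower for estradiol in TOP2A. That effect gave 243 and 102 without subtracting controls, and 70 and 12 with input as the only control. With an estimated correlation the human satellites in TOP2A versus TOP2B (adjusted p = 0.303) and ribosomal RNA for estradiol in TOP2B (adjusted p = 0.742) no longer passed. Of the counts with all libraries, 118 stayed within 1.5 times and 40 did not. With a library left out, 122 stayed and 74 did not.

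Leaving out each library in turn, except the TOP2A pair for the estradiol effect on TOP2A, which cannot be estimated without it, higher and lower counts ranged over 12 to 54 and 25 to 127 (TOP2B over input), 14 to 158 and 44 to 440 (TOP2A over input), 13 to 55 and 23 to 130 (GFP over input), 0 to 162 and 0 to 405 (TOP2A versus TOP2B), 0 to 1 and 0 to 0 (antisera), 0 to 256 and 0 to 182 (estradiol on TOP2B), 68 to 528 and 9 to 273 (estradiol on TOP2A), 0 to 0 and 0 to 0 (estradiol in controls), 0 to 5 and 0 to 3 (TOP2B over GFP), and 0 to 137 and 0 to 381 (TOP2A over GFP). The highest counts came without a TOP2A library for comparisons of kinds and without a TOP2B library for estradiol. The lowest that lay above 0 came without an input or GFP library.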

Other observations

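Transition sequence differed between immunoprecipitates and input by chromosome, and the GFP control did so like the TOP2 libraries. Of 23 chromosomes (Y left out), 8 held a larger share of all ct reads than in input in all 8 immunoprecipitates and 10 a smaller one. On chromosome 3 the log2 ratio of shares lay between 0.25 and 0.56, on chromosome 5 between 0.22 and 0.46, and on chromosome 6 between 0.23 and 0.45. On chromosome 7 it lay between -0.45 and -0.22, on chromosome 17 between -0.33 and -0.20, and on chromosome 22 between -0.51 and -0.12. Each library was set against the input of its own treatment, so the 8 ratios share 2 input libraries and are not independent. The input libraries differed from each other by at most 0.019 (log2), and against either of them 8 chromosomes above and 9 below input lay beyond their own input difference.

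Gamma satellites, short GC-rich arrays beside the alpha satellite, took 0.448% ± 0.10 (SD, n = 6) of region reads in TOP2 libraries and 0.295% ± 0.024 (SD, n = 2) in GFP, a difference that did not pass (exact permutation p = 0.143, 28 splits, adjusted p = 0.696 over 13 measures). The share over that in GFP was 1.90 and 1.59 in TOP2A, untreated and treated, 1.59 and 1.05 with antiserum 30400, and 1.24 and 1.72 with antiserum 3535. Input held 0.396% ± 0.0095. Human satellite 1A, an AT-rich array, took 0.353 and 0.398 of its GFP share with antiserum 3535, and 0.950 and 1.73 of it with antiserum 30400, a class difference between the antisera that did not pass with an estimated correlation (camera adjusted p = 0.127). These shares rest on few reads, 89 and 119 with antiserum 3535, 221 and 419 with antiserum 30400, and 248 and 67 in GFP.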
